A study of Mus musculus with 4 samples.

How the data were processed

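Gene expression was measured by RNA sequencing in 4 cultures of the mouse podocyte line MPC, 1 library each. Per the labels, the line is conditionally immortalised, grows at 33 °C with 10% serum and 20 U/ml interferon-gamma, and was differentiated for 7 days at 37 °C without interferon-gamma. Per the labels, the cells carried a control hairpin or a hairpin against Jaml, and glucose-exposed cultures received D-glucose to a final 40 mmol/L, which the design text of the series gives as lasting 24 h. No osmotic control is named in the labels. Per the labels, the libraries followed the TruSeq RNA guide. Per the submitters' processing notes, the tools were CASAVA 1.8 and TopHat2 2.0.6 with build mm10. The deposited table holds an estimated count per Ensembl gene and library, which the authors made from the aligned reads and which carries no scaling between libraries. The counting tool and the annotation are not given in the sources used here. The table's columns are named by condition. The column for control cells and the one for control cells in high glucose name no hairpin, and were mapped by name to sh-NC and sh-NC/HG. The design text of the series speaks of 4 treated and 4 untreated samples, while 4 libraries were analysed here.

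The table had 56393 genes, of which 27916 were 0 in all 4 libraries, and 1 line without a gene, which was left out. Low values piled up at multiples of 4, with 1.51 to 2.1 times as many genes at 4, 8 and 12 as at the neighbouring even values in each of the 4 libraries, so 4 units were taken as 1 sequenced fragment. Counting intervals and floors use the values divided by 4, and ratios use the values as deposited. The floor is 3 fragments, or 12 units, per library. Gene symbols and positions came from GENCODE release M21, which matched 55394 of the genes and left 999 unmatched. Exon bases shared with another gene of the table were computed from the same annotation, because reads there can be assigned to either gene.

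Counts were scaled with edgeR's TMM factors (R 4.3.3, edgeR 4.0.16), and log2 ratios used a prior count of 1. Genes with a mean count of at least 50 over the 4 libraries entered. A gene counted as apart in a pair of libraries at a ratio of at least 2-fold in either direction. Each named ratio has an exact 95% interval (Clopper-Pearson, conditional on the sum of both counts). Each pair was described without a test, since 1 library per group has no spread. The additive model with terms for hairpin and glucose was fitted with edgeR's quasi-likelihood functions, with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. Its error is the disagreement between the 2 hairpins or the 2 glucose levels. Limma 3.58.1 (voom) and DESeq2 1.42.0 were run on the same model. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

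Comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule took Jaml, a fixed group of regulators and markers (among them Srebf1, Srebf2, Sirt1, Fasn, Acaca, Scd1, Nphs1, Wt1, Synpo and Txnip), the 6 highest and 6 lowest ratios of each pair, the 8 largest shared differences per direction for glucose and for hairpin, the 5 largest differences between hairpins per direction, and up to 2 highest and 2 lowest members of each list that stood apart. Genes outside the lists needed a mean count of at least 100. Some genes that the rule took are not reported here. The 28 lists covered lipid synthesis, cholesterol synthesis, fatty acid oxidation, lipid uptake and storage, SIRT1 and AMPK, podocyte markers, junction adhesion, glycolysis, glucose-responsive genes, the hyperosmotic response, ER stress, NF-kB, type I interferon, interferon-gamma and MHC class I, cell cycle, p53, matrix and TGF-beta, NRF2, autophagy, nuclear and mitochondrial respiratory genes, ribosomal proteins, immediate-early genes, histones, and leukocyte, endothelial, tubule and mesangial markers. They hold 647 genes, 9 of them in more than 1 list. List members were matched by symbol, and Aldoa and Igsf5 each name 2 Ensembl genes past the count minimum, both of which were kept. The tubule list had 4 members past the count minimum, under the 5 required, so its members are given singly. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean level, and the middle 95% was taken as the random range. Random members were drawn singly, so this range leaves out that genes of a list can move together. Lists were tested over the additive model with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

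The additive test was tested on simulated data for the glucose main effect over 14187 genes, with 50 genes changed at each of 4 sizes. At a dispersion of 0.05 it called 12 of 50 genes changed 2-fold and 50 of 50 at 4-fold, 8-fold and 16-fold, with 8 unchanged genes called. At a dispersion of 0.02 it called 46 of 50 at 2-fold and 50 of 50 at each larger size, with 16 unchanged genes called. All simulated genes had the same dispersion and equal glucose effects in both hairpins, so these shares can overstate what the test finds in the data. In the data Hba-a1, 41.0-fold and 66.7-fold lower in the 2 glucose pairs, had an adjusted p of 0.369 by edgeR's quasi-likelihood test. The overlap of glucose-moved genes with hairpin differences was compared with 100 simulated data sets with no effect and 100 in which both hairpins shared the sh-NC glucose effect.

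Alternatives were total-count scaling and DESeq2 size factors, count minimums of 10, 200 and none, a prior count of 5, a 3-fold and a 1.5-fold rule, random lists without matching, a model without the covariate, limma-voom and DESeq2. Added after the values were seen were restricting to genes with under 10% of shared exon bases, dividing the counts by 4, intervals from undivided values, applying the count minimum without sh-NC/HG, keeping 1 Ensembl gene per symbol in a list, and leaving out each library in turn from a model without the covariate. Raw reads, splicing and transcript forms were not analysed here.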

Results

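RNA from a conditionally immortalised mouse podocyte line was sequenced in 4 libraries, which paired each of 2 hairpins with each of 2 glucose conditions. Podocytes are the epithelial cells that wrap the glomerular capillaries and carry the slit diaphragm of the kidney filter. The cells carried a control hairpin (sh-NC) or a hairpin against Jaml (sh-JAML), and were kept in medium without or with added D-glucose (sh-NC/HG and sh-JAML/HG, final 40 mmol/L, 24 h). Each of the 4 groups had 1 library, so the design has no replicates. The deposited counts summed to 80599238 in sh-NC, 94341975 in sh-NC/HG, 79330461 in sh-JAML and 83551812 in sh-JAML/HG. Between 23148 and 23736 genes had a count above 0 in a library, and 14187 genes with a mean count of at least 50 entered the comparisons. Levels are TMM-scaled CPM, each ratio is followed in parentheses by its exact 95% counting interval, and gene positions are on mm10. Intervals and floors cover counting error only and leave out the variation between cultures.

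Jaml, the junction adhesion molecule-like gene that the hairpin was aimed at, had no count in any of the 4 libraries. It lies on chromosome 9 from 45079183 to 45108534 (ENSMUSG00000048534). A count of 0 allowed up to 0.151 CPM in sh-NC, 0.129 CPM in sh-NC/HG, 0.150 CPM in sh-JAML and 0.142 CPM in sh-JAML/HG (3 fragments per library), so a reduction by the hairpin could not be measured. The keratin genes Krt8 and Krt18 had at most 42 and 4 units in a library, which is low for a cultured kidney epithelial line. Whether reads of some genes, Jaml and Nphs1 among them, were lost in counting was not tested. Of the podocyte markers, Synpo, which encodes the actin-binding protein synaptopodin, stood at 218 CPM in sh-NC, 247 CPM in sh-NC/HG, 172 CPM in sh-JAML and 180 CPM in sh-JAML/HG. Nes, which encodes the intermediate filament nestin of mature podocytes, stood between 394 and 620 CPM. The slit diaphragm gene Nphs1 (nephrin) had counts of 35, 18, 18 and 17 in that order of libraries. Wt1, the podocyte transcription factor, stood between 0.632 and 1.17 CPM. Of the 14 listed tubule epithelial markers, 4 were past the count minimum, and these were present in all 4 libraries. Cdh16, a kidney cadherin, stood between 437 and 737 CPM, the endocytic receptor gene Lrp2 between 232 and 421 CPM, and the kidney transcription factor gene Pax8 between 173 and 191 CPM. Cubn, which encodes the partner receptor of megalin, was the remaining tubule gene past the count minimum and stood between 1.90 and 2.87 CPM.

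The sh-NC/HG and sh-NC libraries address what high glucose does in podocytes with the control hairpin. Several inflammatory genes were higher in sh-NC/HG. Nos2, the inducible nitric oxide synthase gene on chromosome 11 (78920787 to 78960254), was 99.4-fold higher (22 to 4948), from 5 units in sh-NC, which is under the floor of 12 units. The neutrophil chemokine gene Cxcl5 was 44.9-fold higher (19.0 to 139), Lcn2, which encodes the iron-binding acute phase protein lipocalin-2, was 34.5-fold higher (15.9 to 83.5), and the acute phase gene Saa3 was 25.5-fold higher (9.73 to 95.4). Of the 23 measured NF-kB cytokine and chemokine genes, 7 were at least 2-fold higher and 0 at least 2-fold lower, 16 were above 0 and 7 below, and the median log2 ratio was 0.39. Among them, and named after their values were seen, Cxcl1 was 10.6-fold higher (8.93 to 12.5) and the central complement gene C3 was 10.2-fold higher (9.51 to 11).

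Antiviral interferon-stimulated genes were also higher in sh-NC/HG as a group: all 27 had a ratio above 1, 14 were at least 2-fold higher, and their median log2 ratio was 1.10. Mx1, an antiviral GTPase gene on chromosome 16 (97447035 to 97462907), was 6.21-fold higher (5.06 to 7.62), its neighbour Mx2 3.30-fold (2.96 to 3.68), the nucleic acid sensor gene Zbp1 3.24-fold (2.98 to 3.53) and the interferon regulator gene Irf7 2.39-fold (2.27 to 2.51). The interferon-gamma and MHC class I list had a median of 0.43, with 24 of 27 members above 0. Within it Irf8, Gbp6 and Iigp1 were 2.62-fold (2.36 to 2.92), 2.46-fold (2.08 to 2.93) and 2.29-fold (2.18 to 2.40) higher. Ciita, the master regulator of MHC class II genes (chromosome 16, 10480059 to 10528418), went the other way and was 15.6-fold lower (7.27 to 39.8), as was the class II gene H2-Aa, 8.28-fold lower (4.19 to 21.3).

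Glycolysis genes were higher with glucose in the sh-NC cells, with a median log2 ratio of 0.45 over 22 members, 18 of them above 0. Ldha, the lactate dehydrogenase A gene on chromosome 7 (46841475 to 46855627), was 2.55-fold higher (2.48 to 2.62), the aldolase gene Aldoc 9.71-fold (4.52 to 25) and the hexokinase gene Hk2 1.73-fold (1.53 to 1.96). Of the 18 glucose-responsive, polyol, hexosamine and pentose genes, with a median of 0.20, Txnip, the thioredoxin-interacting protein gene that responds to glucose, was 1.61-fold higher (1.54 to 1.68). Cell cycle genes had a median of 0.34 with 29 of 32 above 0, among them the proliferation marker Mki67 at 1.48-fold (1.43 to 1.53) and the topoisomerase gene Top2a at 1.54-fold (1.49 to 1.59). Endothelial markers (5 measured) had a median of 0.71, with Flt1, a receptor gene for VEGF, 3.72-fold higher (2.29 to 6.44).

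Lower in sh-NC/HG were the p53 target and apoptosis genes, with a median log2 ratio of -0.45 and 14 of 20 below 0. The death genes Pmaip1 and Bbc3 were 2.06-fold (1.92 to 2.22) and 1.77-fold (1.64 to 1.92) lower. The matrix and TGF-beta response list went both ways, with 5 of 29 members at least 2-fold higher, 3 at least 2-fold lower and a median of -0.19. The matricellular gene Ccn2 was 2.48-fold lower (2.38 to 2.59) and the fibronectin gene Fn1 1.88-fold lower (1.85 to 1.91), while the collagen gene Col6a1 was 3.21-fold higher (3.04 to 3.39) and the gelatinase gene Mmp9 5.43-fold higher (2.77 to 11.1). Podocyte markers had a median of -0.28, with 3 of 24 at least 2-fold lower. Thsd7a, which encodes a podocyte surface antigen in membranous nephropathy, was 7.74-fold lower (5.96 to 10.4), and Col4a3, a chain gene of the mature glomerular basement membrane, 3.64-fold lower (1.31 to 13.1). Fatty acid oxidation genes had a median of -0.15 with 17 of 24 below 0. All 13 mitochondrially encoded genes were below 0, with a median of -0.74 and mt-Nd2 2.95-fold lower (2.88 to 3.02). Replication-dependent histones had a median of -1.22, and 8 of the 11 measured members were at least 2-fold lower. These last 2 lists were fixed in advance as signs of RNA quality and of poly(A) selection, and they moved in the same library as the interferon-stimulated genes.

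Across the 14187 genes, 660 were at least 2-fold higher and 464 at least 2-fold lower in sh-NC/HG than in sh-NC, and 13 of 27 gene lists had a median outside the middle 95% of 10000 random lists matched on expression. Random lists hold genes drawn singly, so in every pair a list of co-regulated genes can leave this range by chance more often than they do. With 1 library per group no test applies to this pair. The sh-NC/HG library stood apart from the rest: 617 genes were at least 2-fold higher and 357 lower in it than the mean of the other 3 libraries, against 160 and 196 for sh-NC, 126 and 206 for sh-JAML, and 129 and 241 for sh-JAML/HG.

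**Figure D1:**
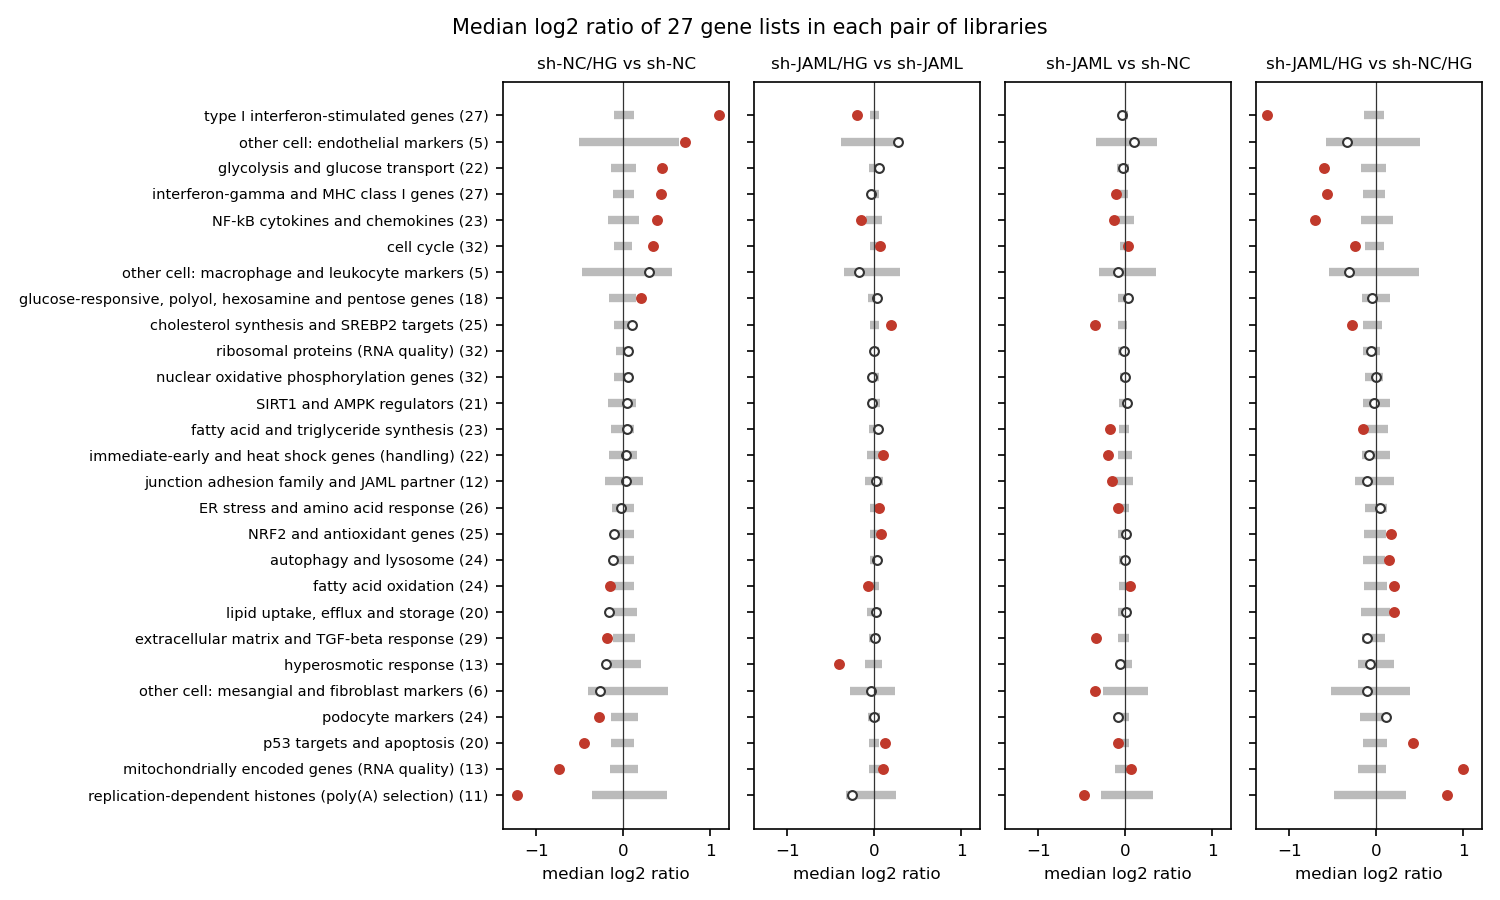
Median log2 ratio of each gene list (number of measured members in parentheses) in each pair of libraries; grey bars are the middle 95% of 10000 random lists matched on expression, filled red points lie outside the bar and open points inside it. The interferon-stimulated list stood at 1.10 in sh-NC/HG against sh-NC, -0.20 in sh-JAML/HG against sh-JAML, -0.04 in sh-JAML against sh-NC and -1.26 in sh-JAML/HG against sh-NC/HG.

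The sh-JAML/HG and sh-JAML libraries ask the same question in cells with the Jaml hairpin. Osmotic stress genes were lower with glucose there: all 13 measured members of the hyperosmotic list had a ratio below 1, 2 were at least 2-fold lower and the median log2 ratio was -0.40. The water channel gene Aqp1 was 2.95-fold lower (2.81 to 3.11), the inducible heat shock gene Hspa1b 2.28-fold lower (2.01 to 2.58), the myo-inositol transporter gene Slc5a3 1.90-fold lower (1.69 to 2.13) and the aldose reductase gene Akr1b3 1.81-fold lower (1.71 to 1.91). Cholesterol synthesis genes were slightly higher, with a median of 0.19 and 22 of 25 above 0. Sqle, the squalene epoxidase gene on chromosome 15 (59315077 to 59331192), was 1.82-fold higher (1.73 to 1.91) and the HMG-CoA synthase gene Hmgcs1 1.40-fold higher (1.36 to 1.44).

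Immune genes lay on the other side of 0 in this pair. Of the 27 interferon-stimulated genes 26 had a ratio below 1, with a median log2 ratio of -0.20 and 0 members at least 2-fold lower. Mx1 was 1.74-fold lower (1.28 to 2.37) and Mx2 1.51-fold lower (1.30 to 1.76), and Oasl2, a gene of the oligoadenylate synthase family, was the exception at 1.53-fold higher (1.45 to 1.61). The NF-kB list had a median of -0.15 (-0.12 with members at 0 set to their bound). Its largest member difference at a well-counted level was in Cx3cl1, the fractalkine gene, 5.63-fold lower (5.04 to 6.30). The p53 target list had a median of 0.12 and the mitochondrially encoded genes 0.10. Small list medians outside the random range were 0.07 for cell cycle genes, 0.08 for NRF2 and antioxidant genes, 0.06 for ER stress and amino acid response genes, 0.10 for immediate-early and heat shock genes and -0.07 for fatty acid oxidation genes. Psat1, a serine synthesis gene of the ER stress and amino acid list, was 1.48-fold higher (1.39 to 1.59), the antioxidant gene Gpx1 was 1.73-fold higher (1.61 to 1.88), and the glutathione synthesis gene Gclm was 1.44-fold lower (1.35 to 1.53).

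In sh-JAML/HG against sh-JAML, 186 genes were at least 2-fold higher and 222 at least 2-fold lower, and 11 of 27 lists lay outside the random range. No test applies to this pair either. The sh-JAML library also enters sh-JAML against sh-NC, with opposite sign, so a shift of it alone would move lists in both pairs. Simulated libraries with no effect, drawn at the common dispersion of 0.0483 that edgeR estimated with the difference between hairpins as error, had a mean of 454 genes at least 2-fold apart in sh-JAML/HG against sh-JAML and 453 in sh-NC/HG against sh-NC. That dispersion was fitted over all 4 libraries, sh-NC/HG among them. Quartiles of the log2 ratios were -0.13 and 0.11 in sh-JAML/HG against sh-JAML, and -0.23 and 0.24 in sh-NC/HG against sh-NC. The dispersion can thus be too wide for the sh-JAML pair, so 454 does not show how many genes chance gives there.

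Taking both hairpins together asks which glucose differences appeared in 2 pairs of libraries that share no library. Globin genes, which encode the oxygen carrier of red cells, were almost absent with glucose in both pairs. Hbb-bs was at 10.6 CPM in sh-NC and 11.8 CPM in sh-JAML. It was 329-fold lower in sh-NC/HG (43.7 to 9777), where it had 3 units, under the floor. In sh-JAML/HG it had 0 and was 83.2-fold lower with 0 set to the floor (67.2-fold or more by its counting interval). Hba-a1 was 41.0-fold (19.6 to 103) and 66.7-fold (27.4 to 262) lower. Tmem170b, a membrane protein gene on chromosome 13 (41605907 to 41641355), was 10.3-fold (7.86 to 13.6) higher in sh-NC/HG and 6.06-fold (4.73 to 7.75) higher in sh-JAML/HG. Xpnpep3, a mitochondrial aminopeptidase gene on chromosome 15 (81400138 to 81457482), was 3.15-fold (2.76 to 3.60) and 3.78-fold (3.29 to 4.36) higher, and the cytokine signalling suppressor gene Socs6 2.48-fold (2.14 to 2.87) and 2.31-fold (2.02 to 2.64). Pheta1, an endosomal trafficking gene, was 5.79-fold (4.58 to 7.31) and 6.15-fold (4.82 to 8.02) lower. Kcnj2, an inward rectifier potassium channel gene, was 4.93-fold (2.43 to 11) and 6.39-fold (2.97 to 15.5) lower, and the peptidase gene Usp29 14.7-fold (8.81 to 26.2) and 4.43-fold (3.18 to 6.41) lower.

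Members of the fixed lists that lay on the same side in both pairs included the osmotic stress genes Slc5a3, 2.03-fold lower in sh-NC/HG (1.82 to 2.27), and Hspa1b, 1.98-fold lower (1.75 to 2.25), beside the values for sh-JAML/HG. Pmaip1, the NOXA death gene, was 2.06-fold and 1.8-fold lower, Cd74, the MHC class II invariant chain gene, 1.45-fold (1.37 to 1.54) and 1.48-fold (1.39 to 1.57) lower, and Sqle 2.07-fold (1.99 to 2.16) and 1.82-fold higher. Of the gamma-protocadherin genes, which encode cell adhesion proteins of 1 cluster on chromosome 18, Pcdhgb4 (37720369 to 37841870) was 904-fold (250 to 7472) and 999-fold (207 to 6190) higher, from 8 and 6 units, which are under the floor, and Pcdhgc3 9.01-fold (7.85 to 10.4) and 11.5-fold (9.69 to 13.8) higher. The cluster did not move as 1: of its 16 measured members 3 were at least 2-fold higher and 9 lower in sh-NC/HG, and 4 higher and 3 lower in sh-JAML/HG, and Pcdhga5 was 10.6-fold (4.73 to 31.1) and 10.8-fold (1.5 to 458) lower, to 4 units in sh-JAML/HG, under the floor. Pcdhgb4 and Pcdhgc3 share 38.3% and 66.9% of their exon bases with others of the cluster, so the assignment of their counts is uncertain. Summed over the cluster, unscaled counts were 8464 in sh-NC and 19786 in sh-NC/HG, and 8356 in sh-JAML and 15410 in sh-JAML/HG. That is a far smaller rise than that of Pcdhgb4.

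In the additive model over both hairpins, edgeR's quasi-likelihood test with 1 residual degree of freedom called 1 gene for glucose, Pcdhgb4, which rose by 9.86 on the log2 scale (SE 0.20, Benjamini-Hochberg adjusted p = 0.0188), with a higher level in 2 of 2 pairs. At an unadjusted p under 0.05 there were 397 genes; DESeq2 called 53 genes (22 higher, 31 lower) and limma-voom 0. The call for Pcdhgb4 ended without the count minimum and among genes with under 10% of shared exon bases, which leave it out. DESeq2's adjusted p was 8.58e-19 for Tmem170b, 5.34e-13 for Xpnpep3, 1.58e-18 for Pheta1, 1.57e-05 for Sqle, 0.00105 for Slc5a3 and 0.000215 for Pmaip1, and it was above 0.05 for Kcnj2 (0.0654) and Cd74 (0.265). EdgeR's adjusted p was 0.483 for each of Tmem170b, Xpnpep3 and Pheta1. Across genes, which are not independent replicates, the 2 glucose ratios had a Pearson r of 0.059 and a Spearman rho of 0.041. There were 47 genes at least 2-fold higher in both pairs (8.7 expected from independent lists) and 37 lower in both (7.3 expected), beside 51 and 28 genes that went opposite ways (10.3 and 6.1 expected).

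**Figure D2:**
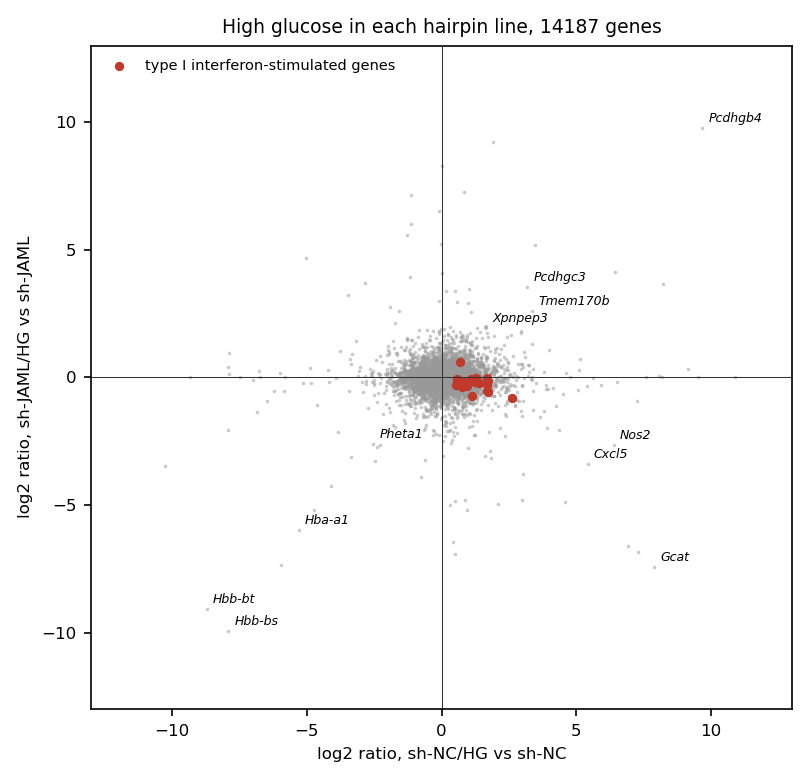
Log2 ratio with high glucose in the control-hairpin cells (horizontal) and the Jaml-hairpin cells (vertical), 1 grey point per gene, 14187 genes; red points are the 27 type I interferon-stimulated genes. The globin genes lie at the lower left and Pcdhgb4 at the upper right, and the interferon-stimulated genes lie right of 0, with a median of 1.10 on the horizontal axis and -0.20 on the vertical.

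The sh-JAML and sh-NC libraries address what the Jaml hairpin does at the basal glucose level, and the series title names lipid metabolism as its subject. Sterol synthesis genes were lower with the Jaml hairpin: 24 of 25 cholesterol synthesis and SREBP2 target genes had a ratio below 1, with a median log2 ratio of -0.35 and 0 members at least 2-fold lower. Hmgcs1 was 1.33-fold lower (1.30 to 1.37) and Sqle 1.31-fold (1.25 to 1.38). Srebf2, which encodes the sterol-sensing transcription factor SREBP2 (chromosome 15, 82147181 to 82205379), was 1.18-fold lower (1.15 to 1.21). Fatty acid and triglyceride synthesis genes had a median of -0.17, with 17 of 23 below 0. The desaturase genes Scd1 and Scd2 were 1.31-fold (1.26 to 1.36) and 1.39-fold (1.35 to 1.42) lower and the elongase gene Elovl6 1.47-fold lower (1.37 to 1.57), while Srebf1, the gene for the fatty acid regulator SREBP1, was 1.07-fold higher (1.01 to 1.14). The synthase genes Fasn and Acaca were 1.14-fold (1.11 to 1.17) and 1.10-fold (1.04 to 1.17) lower. Sirt1, a deacetylase gene of energy sensing, was 1.13-fold lower with an interval that held no difference (0.984 to 1.29).

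Matrix and TGF-beta response genes were lower as well, with 26 of 29 below 0 and a median of -0.34: Ccn2 was 1.87-fold lower (1.8 to 1.95) and the smooth muscle actin gene Acta2 1.47-fold (1.44 to 1.5). The mesangial and fibroblast list, which shares 2 of its genes with other lists, had a median of -0.35 over 6 members. Immediate-early and heat shock genes had a median of -0.20 and the NF-kB list -0.13, in which the inhibitor gene Tnfaip3 was 2.02-fold lower (1.77 to 2.31) and Cx3cl1 5.03-fold higher (4.51 to 5.61). The chaperone gene Hspa5 was 1.93-fold lower (1.88 to 1.99) in an ER stress list with a median of -0.08. The junction adhesion list, which holds Cxadr, the gene for the receptor that binds JAML, had a median of -0.15 over 12 members, and -0.13 over 11 with only the better counted of the 2 Ensembl genes named Igsf5, close to the edge of the random range at -0.12. Cxadr itself was 1.12-fold lower (1.09 to 1.16). Histones had a median of -0.47, interferon-gamma and MHC class I genes -0.10, p53 targets -0.08, fatty acid oxidation genes 0.06, mitochondrially encoded genes 0.07 and cell cycle genes 0.03, all outside the random range. Of other RNAs without a poly(A) tail, Rn7sk was 5.65-fold (2.97 to 11.9), Rn7s1 2.83-fold (2.12 to 3.80) and Rn7s2 2.77-fold (2.08 to 3.71) higher. The Snora genes measured had intervals that held no difference. The interferon regulator gene Irf1 was 1.82-fold higher (1.68 to 1.98), the cyclin gene Ccnd1 1.69-fold lower (1.54 to 1.85) and Ppargc1a, the coactivator gene of mitochondrial biogenesis, 1.51-fold higher (1.15 to 1.98). Podocyte markers (-0.08) and interferon-stimulated genes (-0.04) lay inside the random range.

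In sh-JAML against sh-NC, 186 genes were at least 2-fold higher and 198 lower, and 14 of 27 lists lay outside the random range. Of the 14187 genes simulated with no effect, a mean of 459 were at least 2-fold apart in this pair. The dispersion was again the one fitted with sh-NC/HG, and quartiles of the log2 ratios were -0.11 and 0.12 here. The simulated count can thus be too high for this pair and does not show how many genes chance gives. A single hairpin against Jaml was compared with a single control line, so the hairpin and any other difference between the lines, such as clone or passage, were not separated. A shift of the sh-JAML library alone would also give opposite signs here and in sh-JAML/HG against sh-JAML. Such lists were cholesterol synthesis (-0.35 and 0.19), immediate-early (-0.20 and 0.10), ER stress (-0.08 and 0.06) and p53 targets (-0.08 and 0.12). In sh-JAML/HG against sh-NC/HG, which does not hold that library, these lists had -0.28, -0.08, 0.05 and 0.42.

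The sh-JAML/HG and sh-NC/HG libraries address whether glucose-exposed podocytes differ with the Jaml hairpin. Cxcl5, Nos2 and Saa3, which stood out in sh-NC/HG, had a count of 0 in sh-JAML/HG. With 0 set to the floor, Cxcl5 was 79.5-fold lower (64.2-fold or more by its counting interval) and Nos2 44.0-fold (35.4-fold or more). Saa3 was 36.2-fold lower with 0 set to the floor and no counting error allowed for. Lcn2 was 23.6-fold lower (13.3 to 52.2). The NF-kB list had a median log2 ratio of -0.70 with 9 of 23 members at least 2-fold lower. All 27 interferon-stimulated genes were lower, 20 of them at least 2-fold, with a median of -1.26, Mx1 10.4-fold lower (8.09 to 13.4), Mx2 5.13-fold (4.53 to 5.84), Zbp1 3.89-fold (3.56 to 4.25) and Ifi44 3.51-fold (3.29 to 3.76). Interferon-gamma and MHC class I genes had a median of -0.56, with 24 of 27 below 0, the chemokine gene Cxcl10 2.43-fold lower (2.32 to 2.55) and the GTPase genes Tgtp1 and Iigp1 3.20-fold (3.04 to 3.38) and 3.15-fold (2.98 to 3.32) lower. Ciita and H2-Aa were 14.1-fold (6.61 to 36.3) and 10.1-fold (5.2 to 25.8) higher. The leukocyte genes Ptprc, Adgre1, Cd53, Laptm5 and Tyrobp also had a count of 0 in sh-JAML/HG. In sh-NC/HG they had 16, 48, 18, 25 and 21 units. The interval held no difference for Ptprc, Cd53 and Tyrobp, and did not for Adgre1 (2.52-fold or more lower) and Laptm5 (1.07-fold or more). Lyz2, the lysozyme gene of macrophages, was above the floor in sh-NC/HG and under it in sh-JAML/HG, with levels given among the other observations. Csf1r (4665 and 4759 units), Fcer1g (33 and 22) and Coro1a (17 and 14) did not vanish. A loss of leukocyte RNA in sh-JAML/HG was not tested.

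Glycolysis genes had a median of -0.60 with 17 of 22 below 0, Ldha 2.83-fold (2.75 to 2.91) and Hk2 1.89-fold (1.67 to 2.15) lower, and cell cycle genes had a median of -0.24. Cholesterol synthesis genes were again lower, with 23 of 25 below 0 and a median of -0.28: Srebf2 was 1.60-fold lower (1.57 to 1.64) and Sqle 1.5-fold (1.45 to 1.55). Fatty acid synthesis genes went both ways, with 13 of 23 below 0, 10 above 0 and a median of -0.15. Fasn was 1.27-fold lower (1.24 to 1.30), Srebf1 1.18-fold lower (1.11 to 1.25) and Acaca 1.14-fold lower (1.08 to 1.20), while the lipin gene Lpin1 was 1.71-fold higher (1.57 to 1.85) and the malic enzyme gene Me1 1.62-fold higher (1.5 to 1.76). Lipid uptake, efflux and storage genes had a median of 0.20, with the lipid droplet coat gene Plin4 4.61-fold (3.53 to 6.13) and the cholesterol efflux pump gene Abca1 4.21-fold (2.49 to 7.55) higher, and fatty acid oxidation genes a median of 0.20 with 16 of 24 above 0. Sirt1 was 1.32-fold higher (1.16 to 1.5).

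Mitochondrially encoded genes were all above 0 in sh-JAML/HG against sh-NC/HG, with a median of 1.0, 7 of 13 at least 2-fold higher and mt-Nd2 3.30-fold higher (3.23 to 3.38). Histones had a median of 0.81, p53 targets 0.42 with Bbc3 2.05-fold higher (1.90 to 2.22), NRF2 and antioxidant genes 0.17, and autophagy and lysosome genes 0.15. The NADPH oxidase gene Nox4 was 2.67-fold higher (2.38 to 3.01) and the autophagy gene Gabarapl1 1.88-fold higher (1.79 to 1.96). Thsd7a was 8.14-fold higher (6.28 to 10.9), within a podocyte list with a median of 0.11 that lay inside the random range, and Aqp1 3.10-fold lower (2.94 to 3.25). In total 399 genes were at least 2-fold higher and 678 lower, and 14 of 27 lists lay outside the random range. All of these ratios hold the sh-NC/HG library, and no test applies to the pair.

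**Figure D3:**
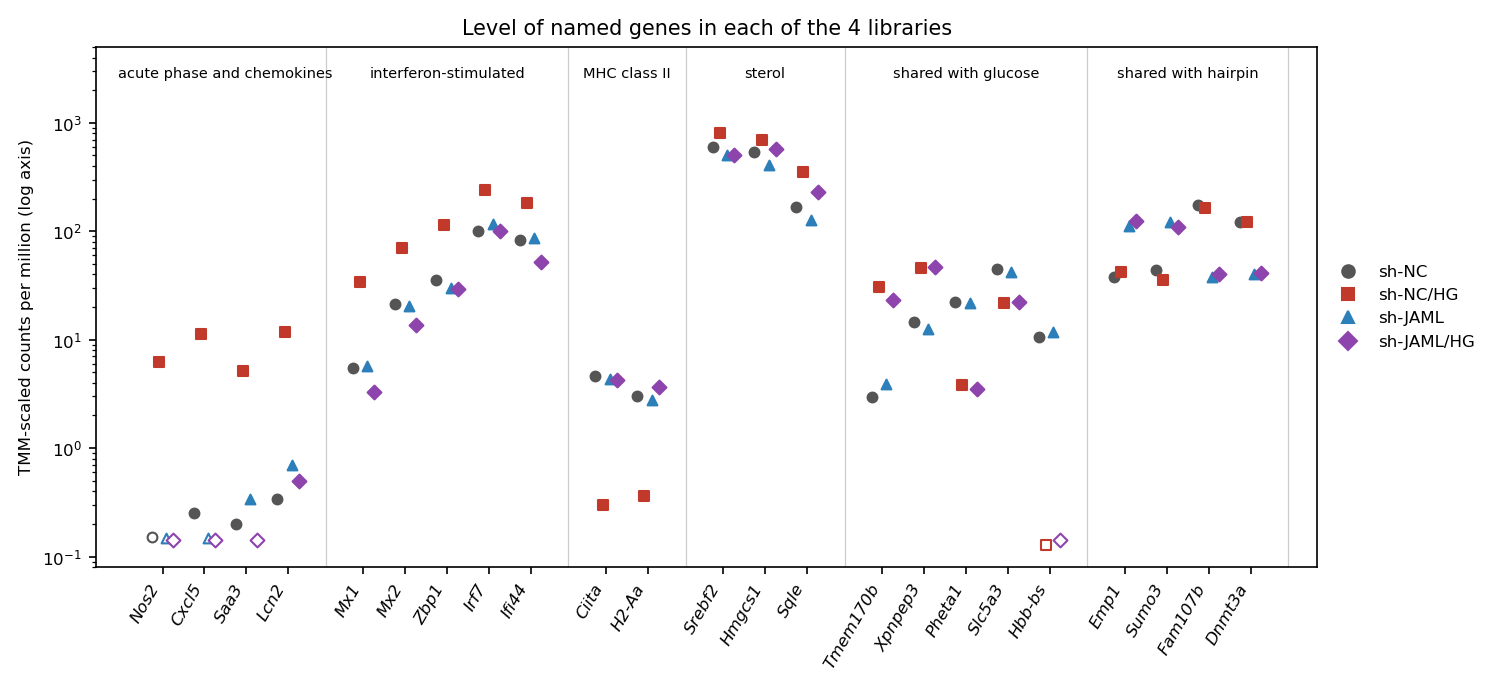
TMM-scaled CPM (log axis) of named genes in each of the 4 libraries, 1 symbol per library; open symbols are levels under the floor of 3 fragments, drawn at the floor. The acute phase, chemokine and interferon-stimulated genes stood highest in sh-NC/HG (Nos2 at 6.25 CPM and Mx1 at 34.2 CPM) and Ciita stood lowest there (0.300 CPM), while Emp1 was at 112 and 125 CPM in sh-JAML and sh-JAML/HG and at 38.0 and 41.9 CPM in sh-NC and sh-NC/HG.

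Differences between the hairpins that were alike with and without added glucose included several well-counted genes. Fam107b, an actin-associated gene on chromosome 2 (3570488 to 3782142), was 4.55-fold lower without (4.20 to 4.92) and 4.07-fold lower with glucose (3.78 to 4.38) in the sh-JAML cells. Dnmt3a, the de novo DNA methyltransferase gene on chromosome 12 (3806007 to 3914443), was 3.02-fold (2.79 to 3.27) and 2.91-fold (2.70 to 3.15) lower. Emp1, an epithelial membrane protein gene on chromosome 6 (135362545 to 135383173), was 2.95-fold (2.72 to 3.21) and 2.99-fold (2.77 to 3.22) higher, the ubiquitin-like modifier gene Sumo3 2.80-fold (2.59 to 3.03) and 3.08-fold (2.85 to 3.34) higher and the cyclin gene Ccnd3 2.58-fold (2.31 to 2.90) and 2.36-fold (2.13 to 2.62) higher. Ccnd1, another cyclin gene, was lower in both, 1.69-fold and 1.75-fold (1.61 to 1.89). Nnt, the mitochondrial transhydrogenase gene, was 3.74-fold (3.05 to 4.58) and 3.07-fold (2.54 to 3.73) lower, but shares 47.4% of its exon bases with another gene. EdgeR's quasi-likelihood test in the additive model called 0 genes for the hairpin, with 400 at an unadjusted p under 0.05. The smallest adjusted p was 0.617, reached by Fam107b (log2 -2.11, SE 0.12), Dnmt3a, Emp1 and Sumo3. DESeq2 called 48 genes (24 higher, 24 lower), with adjusted p of 6.79e-28 for Fam107b and 6.45e-15 for Dnmt3a, and limma-voom called 0. Across genes the 2 hairpin ratios had a Pearson r of 0.007 and a Spearman rho of 0.039, and 24 genes were higher and 48 lower in both pairs (5.2 and 9.5 expected), beside 38 and 26 that went opposite ways (8.9 and 5.6 expected).

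Over the additive model the camera set test with a preset correlation of 0.01 called 10 of 27 lists for glucose. Interferon-stimulated genes (adjusted p = 5.66e-07), cell cycle (5.66e-07), glycolysis (0.000138), cholesterol synthesis (0.000361), interferon-gamma (0.00685) and endothelial genes (0.0335) were called up, and the hyperosmotic list (3.93e-06), histones (2.20e-05), mitochondrially encoded genes (0.00041) and fatty acid oxidation (0.0450) down. None held with an estimated correlation, where the smallest value was adjusted p = 0.63 with an estimated correlation, and none by fry (smallest adjusted p = 0.458). The hyperosmotic call rested on -0.20 in the sh-NC pair and -0.40 in the sh-JAML pair, and cholesterol synthesis on 0.10 and 0.19. For both lists the sh-NC value lay inside the random range. Glycolysis (0.45 and 0.06), histones (-1.22 and -0.26) and endothelial genes (0.71 and 0.27) lay inside it in the sh-JAML pair. The interferon-stimulated list (1.10 and -0.20), the interferon-gamma list (0.43 and -0.04) and the mitochondrially encoded genes (-0.74 and 0.10) had opposite signs in the 2 pairs. For the hairpin camera called 14 lists, none of which held with an estimated correlation or by fry. Down were cholesterol synthesis (1.05e-13), interferon-stimulated genes (8.58e-13), interferon-gamma (9.27e-06), NF-kB (1.63e-05), matrix (5.22e-05), glycolysis (0.000266), cell cycle (0.00427), and at 0.00712 each fatty acid synthesis, immediate-early and mesangial genes. Up were mitochondrially encoded genes (1.96e-06), fatty acid oxidation (0.00797), p53 targets and NRF2 genes (0.0388 each). Without and with glucose, cell cycle genes (0.03 and -0.24) and p53 targets (-0.08 and 0.42) had opposite signs. Most of the difference lay in the pair with sh-NC/HG for interferon-stimulated genes (-0.04 and -1.26), glycolysis (-0.02 and -0.60), NF-kB (-0.13 and -0.70), interferon-gamma (-0.10 and -0.56), NRF2 (0.01 and 0.17) and mitochondrially encoded genes (0.07 and 1.0). The smallest values here were adjusted p = 0.622 with an estimated correlation and 0.613 by fry. The lists for SIRT1 and AMPK regulators, nuclear oxidative phosphorylation, ribosomal proteins, and macrophage and leukocyte markers lay inside the random range in all 4 pairs and were not called, with medians in sh-NC/HG against sh-NC of 0.04, 0.05, 0.06 and 0.30.

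The layout also asks whether genes that moved with glucose in the sh-NC cells lay nearer their basal level with the Jaml hairpin. Of the 660 genes at least 2-fold higher in sh-NC/HG than in sh-NC, 441 (66.8%) were at least 2-fold lower in sh-JAML/HG than in sh-NC/HG, among them Nos2, Mx1, Ldha and Col6a1. Of the 464 lower genes, 262 (56.5%) were at least 2-fold higher, among them Ciita, Thsd7a, Plin4 and mt-Nd2. Both ratios hold the sh-NC/HG library with opposite sign, so chance alone gives an excess: simulations with no effect gave 10.2% and 22.3%, and simulations in which both hairpins shared the sh-NC glucose effect gave 4.0% and 7.85%. The simulations gave all libraries 1 common dispersion, while sh-NC/HG had an SD of 0.64 in log2 from the mean of the other 3 libraries, against 0.41 to 0.45 for the rest. A shift of that library alone raises both shares by construction, so 66.8% and 56.5% do not set a hairpin effect apart from it. In sh-JAML/HG against sh-JAML, which does not hold that library, the median log2 ratio was -0.02 for the 660 genes and -0.03 for the 464. Glucose effects differed at least 2-fold between the hairpins in 602 genes upward and 834 downward, and this difference had no residual degree of freedom and no test.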

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

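For the interferon-stimulated genes the tests of scaling, of a glucose response common to both hairpins and of an event in 1 culture were chosen after the result was seen, as were those of S-phase genes, of Hox genes 2-fold apart, of globin copies and of leukocyte transcripts without Csf1r, and the spread allowed in the test of carry-over. The others were chosen before. For genes or lists whose glucose log2 ratios had opposite signs in the 2 hairpins, the ratio in the sh-JAML cells minus that in the sh-NC cells is given first, and both ratios follow in parentheses. With 1 library per group none of these differences was tested.

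Nos2, the inducible nitric oxide synthase gene, had a difference of -9.03 (6.39 in sh-NC and -2.65 in sh-JAML, from 5 units to 0, both under the floor). Cxcl5, a neutrophil chemokine gene, had -8.81 (5.42 and -3.39, from 9 units to 0), so for these genes a fall in the sh-JAML cells was not shown. The acute phase gene Saa3 had -9.47 (4.59 and -4.88), with 27 units in sh-JAML and 0 in sh-JAML/HG. With 0 set to the floor and no counting error allowed for, its fall was 2.37-fold. Tgfb3, a TGF-beta ligand gene, had -2.94 (1.02 and -1.93). Gcat had -15.3 (7.87 and -7.43), but both ratios run against a count of 0 and are set by the prior count. Their counting intervals bound them only at 14.4-fold or more higher and 11.2-fold or more lower. Exosc6 had 6.51 (-2.83 and 3.69). The gamma-protocadherin genes Pcdhga9 and Pcdhgb1 had -7.03 (2.08 and -4.95) and 9.7 (-5.03 and 4.68). Gcat, Exosc6, Pcdhga9 and Pcdhgb1 share 86.1%, 100%, 37.9% and 54.6% of their exon bases with other genes. Of the lists, NF-kB cytokines and chemokines had -0.54 (0.39 and -0.15), type I interferon-stimulated genes -1.3 (1.10 and -0.20), p53 targets 0.58 (-0.45 and 0.12) and mitochondrially encoded genes 0.84 (-0.74 and 0.10).

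Interferon-stimulated genes stood higher in sh-NC/HG than in sh-NC and slightly lower in sh-JAML/HG than in sh-JAML. Leukocyte RNA is argued against, since 8 leukocyte transcripts summed to 64.0 CPM in sh-NC and 51.9 CPM in sh-NC/HG. That change was -0.34% of the list's summed rise of 3613 CPM. Csf1r alone held 62.1 and 50 CPM, and the 7 others summed to 1.91 CPM in each. Of these 7, Adgre1 (16 to 48 units) was 2.56-fold higher (0.775 to 10.9) and Laptm5 (8 to 25 units) 2.66-fold (0.457 to 25.9). Both intervals held no difference. Scaling is argued against, since a library-wide factor shifts all genes alike and the list's median exceeded that of all genes by 1.10, while the middle 95% of random lists ended at 0.12, and the median was 1.08 after removal of trends on GC content and transcript length. Cells of another origin in the culture cannot be told apart, because the median absolute log2 ratio of 30 Hox genes was 0.24 (SE 0.09; 0.11 in the sh-JAML pair) but 4 of them were at least 2-fold apart, against 0 in that pair, a small share is hidden by the cells' own Hox level, and endothelial markers rose too (0.71). An event in the 1 sh-NC/HG culture other than the glucose and a glucose response common to both hairpins cannot be told apart either, since each group had 1 library and the median of -0.20 in the sh-JAML pair is the value that drew attention, while a response that needs Jaml and a difference in RNA quality or library make-up of sh-NC/HG, where mitochondrial mRNAs (-0.74) and histones (-1.22) moved as well, were not tested.

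Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, stood lower in sh-NC/HG than in sh-NC. The 12 S-phase genes of the cell cycle list, a list already seen to be higher in this pair (0.34), had a median log2 ratio of 0.25. The SE of 0.07 is over genes, not cultures, and 10 of them were above 0. These values argue against fewer cells in S phase, as far as RNA of these genes shows it. Less carry-over of RNA without a poly(A) tail would lower other such RNAs by about the histones' -1.22. The median of 8 such RNAs was 0.20 (SE 0.2 over genes that are not independent), 6 of them above 0 and the lowest at -0.84. Snora68 and Snora24 share 100%, Snora34 66.7%, and Rn7s1 and Rn7s2, with near-equal counts, 49.0% of their exon bases with other genes. Snora57, Rn7sk and Snora31, which share 0%, had 0.2, 0.28 and 0.51, from 65, 44 and 62 units in sh-NC. These values argue against less carry-over for these few low-counted RNAs only. A change in the processing of histone mRNAs was not tested and stays open.

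The globin genes stood lower with glucose in both hairpins. A shift of reads between similar copies, Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt, is argued against, because all 4 were at least 2-fold lower in both pairs. Their sum, which had to be lower too, was 79.0-fold lower in sh-NC/HG (43.9 to 158.8) and 166.3-fold lower in sh-JAML/HG (74.5 to 539). Reads lost to copies outside these 4 were not examined. Erythroid RNA in the libraries without added glucose cannot be told apart from globin expression by the cells, since only 2 of the other erythroid genes were above 12 units there and their sums were 61, 65, 119 and 51 units in sh-NC, sh-NC/HG, sh-JAML and sh-JAML/HG. A difference of the cultures by day or handling that followed the glucose remains open as well, as the labels give no dates.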

How the results depend on the processing

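The restriction to genes with under 10% of shared exon bases, the counts divided by 4, the undivided intervals, the count minimum without sh-NC/HG and the fits on 3 libraries were chosen after the data were seen. Counts of genes at least 2-fold apart followed the count minimum and the size rule, which by construction change how many genes can count. In the order sh-NC/HG against sh-NC, sh-JAML/HG against sh-JAML, sh-JAML against sh-NC, sh-JAML/HG against sh-NC/HG, and glucose effects between hairpins, genes higher and lower were 1564 and 1129, 903 and 873, 856 and 853, 1069 and 1510, and 1576 and 1945 with a mean count of at least 10. They were 338 and 257, 61 and 78, 60 and 77, 214 and 353, and 322 and 432 with a mean count of at least 200. With the 3-fold rule they were 262 and 155, 61 and 80, 67 and 68, 117 and 296, and 219 and 381. Among genes with under 10% of shared exon bases, 113 were higher in sh-JAML than in sh-NC, and the other 9 counts stayed within 1.5 times. All 10 counts stayed within 1.5 times with total-count scaling, with DESeq2 size factors and with a prior count of 5. Without sh-NC/HG in the count minimum, sh-JAML/HG against sh-JAML had 172 higher and 201 lower, and sh-JAML against sh-NC 170 and 178. With the 1.5-fold rule, 933 genes higher with glucose lay lower in sh-JAML/HG and 796 lower ones lay higher. The glucose call of edgeR went from 1 gene to 0 with no filter, 0 with genes with under 10% shared exon bases (which leaves Pcdhgb4 out) and 0 with limma-voom, and to 53 with DESeq2. The unadjusted p was under 0.05 for 498, 325, 435 and 549 genes in these 4. The hairpin call went from 0 to 48 with DESeq2, against 400 genes at an unadjusted p under 0.05 in edgeR, and was 0 with limma-voom. The cause of the gap between tools was not tested. With an estimated correlation and with the self-contained test (fry) 0 lists were called for glucose and 0 for the hairpin, from 10 and 14. With a mean count of at least 200 the Pearson r across genes was 0.159 for the 2 glucose pairs and 0.03 for the 2 hairpin pairs. None of the 912 named log2 ratios reversed, and 16 moved beyond their counting interval with total counts only. Of 135 list medians 0 crossed the edge of the random range with total counts only, while 3 moved inside and 6 outside it with a mean count of at least 10, and 16 moved inside and 3 outside it with no matching. Intervals from undivided values excluded no difference for 754 of 920 named ratios, against 631 from fragments. Leaving out a library leaves the additive model no residual degree of freedom, so each was left out of a fit without the covariate, in which the lone library of a group is assumed to vary like the other group. Calls ranged from 0 to 903 for glucose (14 without sh-NC/HG) and from 0 to 983 for the hairpin (11 without sh-NC/HG). Both maxima came from fits with sh-NC/HG as the lone library of its group. For Jaml and other genes under 12 units in both libraries of a pair no difference was detectable.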

Other observations

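The gene groups of this part were chosen after their values were seen. Antigen presentation genes of MHC class II were lower in sh-NC/HG than in sh-NC, with a median log2 ratio of -2.54 over 7 genes, 4 of them at least 2-fold lower, against -0.01 in sh-JAML/HG versus sh-JAML. Complement genes were higher in sh-NC/HG, with a median of 1.61 and 5 of 7 at least 2-fold higher. C4b, a component of the classical pathway, stood at 0.214, 7.74, 0.262 and 0.319 CPM in sh-NC, sh-NC/HG, sh-JAML and sh-JAML/HG, and C1ra, a protease gene of that pathway, at 5.81, 17.8, 6.82 and 7.89 CPM, while C2, with 46.9% of shared exon bases, was lower in sh-NC/HG, at 0.375 CPM against 2.06 CPM in sh-NC. Of the small leucine-rich proteoglycan genes, which organise collagen fibrils or resemble such genes, the 4 past the count minimum (Dcn, Fmod, Islr and Ogn) were at least 2-fold higher in sh-NC/HG, with a median of 3.46 against -0.11 in the sh-JAML pair, where Islr was 2.12-fold higher with an interval that held no difference (0.948 to 4.94). Of those under the minimum, Bgn (54 to 49 units) and Omd (40 to 32) did not rise and Prelp (5 to 102) did. Ogn, the best counted of them, stood at 23.9, 69.5, 23.7 and 20.6 CPM.

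The metallothionein genes Mt1 and Mt2, which bind zinc and copper, were lower in sh-NC/HG. Mt1 stood at 438, 119, 698 and 909 CPM in the same order of libraries and Mt2 at 109, 41.1, 193 and 241 CPM, so both were also higher in the sh-JAML cells than in sh-NC. Mt2 shares 73.5% of its exon bases with another gene. Of the 2 mitochondrial rRNA genes, mt-Rnr1 had a log2 ratio of 1.20 in sh-NC/HG against sh-NC and mt-Rnr2 0.10, while all 13 mitochondrial mRNAs were below 0 there. Lyz2, the lysozyme gene of macrophages, stood at 2.14, 3.02, 2.02 and 0.0591 CPM, the last under the floor.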
